A study of Homo sapiens with 6 samples.

How the data were processed

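Total RNA of IGROV-1 cells, a human ovarian carcinoma line, was measured on 6 single-colour Illumina bead arrays. Per the labels, 3 samples had received saline and 3 had received CpG-ODN at 10 µM for 24 h. The time of the saline samples is not given in the sources used here. CpG-ODN was the phosphorothioate oligonucleotide ODN1826, a synthetic DNA with unmethylated CpG motifs of the kind that Toll-like receptor 9 binds. How strongly this oligonucleotide acts on the human receptor was not measured here. The group and number of each sample came from its title and its treatment label. Nothing in the labels says that the samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may in part be technical. The chip and position of each array were not given in the sources used here.

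Intensities and detection p-values were used from the non-normalized table. The deposited intensity of each probe was on a linear scale and was neither normalized nor background-subtracted, per the file headers and the values themselves. The submitters' processing notes name BeadStudio, and its version is not given in the sources used here. A detection p-value per probe and array was deposited beside it, per the file headers. It ran in steps of 0.00132, as a rank among control probes would. A second deposited table held normalized intensities on a linear scale, with the method not given in the sources used here. Each of its columns kept the rank order of the same array's non-normalized intensities (rank correlation 1). Quantile normalization of the non-normalized values came within 0.0222 log2 units of it at every probe, without background subtraction. The medians of its 6 columns were 119.5 in each case.

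Non-normalized intensities were background-corrected and quantile normalized on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, with the negative controls inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 17950 of 48803 probes. Probes were named from the platform annotation: 28098 had 1 gene symbol, 13 had several and 20692 had none in that table and stayed unnamed. Symbols were looked up by gene number in RefSeq names of assembly GRCh38.p14, which matched 28059 of the probes with 1 symbol and changed 0 symbols. No coordinates are given, since no build is named for the arrays. Of the kept probes 14524 had 1 symbol. Each gene was represented by its probe with the highest mean, which gave 11040 genes. Of these, 2814 genes had several tested probes, and in 1301 of them the probes gave fold changes of opposite sign.

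CpG-ODN was compared with saline by lmFit and eBayes of limma on all 6 arrays, with group as the sole term, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are CpG-ODN minus saline on the log2 scale, given with the standard error (SE) of the fit, over 3 arrays in each group. The offset draws the fold changes of dim probes towards 0. A probe detected on no array of a group has a bound there: its fold is given as at least the bright group's mean over the mean of the lowest detected signal of the dim group's arrays, or of the probe's own signal where that was higher. The number of arrays limits the precision of every value.

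Shifts of 32 gene lists were tested with camera of limma, with its preset correlation between genes, against all other genes and adjusted over the lists. The lists, the fitted model, the alternatives and the rule for the genes to be named were written before the data were examined, and 7 lists were set to answer the comparison: all DNA repair, TLR9 pathway, NF-kB and inflammatory, interferon-stimulated, mitosis, S-phase and p53 target genes. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. Genes were named by this rule: the 10 genes with the smallest unadjusted p in each direction if no gene passed, the 2 members with the smallest unadjusted p of each list, and 10 genes fixed by name, among them TLR9, MYD88, CXCL8, IL6, CXCL10, IFIT1, BRCA1, CDKN1A and MKI67. The remaining gene of these 10 is not reported here. The value of a gene is that of its brightest probe, and where the other tested probes of a named gene are not given they lay on the same side of 0.

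Before use, the gene test was run on simulated data with the means and spreads of the 11040 genes. With 200 genes changed 2-fold it recovered 89.5% of them with 11 false calls. With 200 genes changed 4-fold it recovered 100% with 18 false calls, and with 200 genes changed 1.5-fold it recovered 0%. When such shifts were added to the normalized log2 values of the measured arrays, 0% of 200 genes were recovered at 1.5-fold, 43% at 2-fold and 99.5% at 4-fold. Both tests shifted values after background correction and offset. The shares recovered therefore leave out the loss of fold change that dim probes undergo before that step.

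The alternatives changed 1 choice at a time: the deposited normalized values, no background correction with signals floored at 16, an offset of 50, scaling to equal medians, no filter, a detection p under 0.01 on all 6 arrays, the mean of a gene's probes, all probes on their own, eBayes with trend and robust, array weights, the replicate number as a block, a fold of at least 1.5, an adjusted p under 0.01, and leaving out each array in turn. A fit without CpG-ODN 1 and 2 together, which leaves 1 CpG-ODN array and assumes that it varies like the saline arrays, and a fit with each array's 75th percentile of log2 signal as a covariate were added after the data had been examined.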

Results

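Transcript levels were measured in IGROV-1 cells, a human ovarian carcinoma line, with 3 arrays in each group. The cells had received either CpG-ODN at 10 µM for 24 h, or saline for a time that is not given. CpG-ODN is a synthetic DNA with unmethylated CpG motifs, and Toll-like receptor 9 is the receptor known for such DNA. Of the 48803 probes on an array, 18790, 17625 and 18265 were detected in saline arrays 1 to 3, and 18426, 17142 and 17543 in CpG-ODN arrays 1 to 3. The median non-normalized intensity lay between 115.5 and 120.8 on all 6 arrays, but most probes were not detected, so it mainly reflects background. The mean intensity was highest on CpG-ODN 1 (712.7) and lowest on CpG-ODN 2 (592.0), against 605.7 to 650.2 on the other arrays. The 75th percentile was 186.7 on CpG-ODN 2 and between 207.6 and 221.3 on the others. The single comparison of the design asked how CpG-ODN changes the transcripts of these tumour cells, and the study is known to concern DNA repair genes in particular.

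No gene passed the test. With limma, 0 of 11040 genes reached an adjusted p under 0.05, 0 higher and 0 lower, and the smallest adjusted p was 1.00. The fold changes were small, with 98.8% of the genes within 1.5-fold either way and only IFIT1 beyond 2-fold. The lowest value belonged to IFIT1, an interferon-induced RNA-binding protein, at −1.32 on the log2 scale. At an unadjusted p under 0.05 there were 395 genes, 214 higher and 181 lower, where 552 would be expected by chance. All 3 CpG-ODN arrays lay on one side of all 3 saline arrays in 1032 genes, or 9.35%, where chance gives 10%. The 95% interval of the fold change lay inside 2-fold for 10532 genes (95.4%) and inside 1.5-fold for 5703 genes (51.7%), with a median SE of 0.19 log2 units.

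The genes with the smallest unadjusted p are given as values that did not pass the test, since each had an adjusted p of 1.00 in limma. Among those with a higher mean in CpG-ODN, the orphan nuclear receptor gene NR0B2 was detected on 0 saline and 3 CpG-ODN arrays and was at least 1.66-fold higher. The serine protease gene KLK13 had a log2 fold change of 0.72 ± 0.15 (SE), and LEFTY1, a secreted inhibitor of Nodal signalling, one of 0.77 ± 0.18. COL8A2, a chain of type VIII collagen, lay at 0.80 ± 0.18, and the matrix protein gene SMOC1 at 0.77 ± 0.20. TIRAP, an adaptor of Toll-like receptor signalling, lay at 0.92 ± 0.23 on its brightest probe and at −0.02 on its other probe. DNHD1, BBOF1, EFHD1 and C15orf39 lay between 0.61 and 0.79, and the other probe of BBOF1 gave −0.20.

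Among those with a lower mean, IFIT1 was 2.5-fold lower on its brightest probe, with a log2 fold change of −1.32 ± 0.25 (SE) and a 95% interval from −1.89 to −0.75. Its other probe, detected on 1 saline and 2 CpG-ODN arrays, gave 0.19. DDX60, an antiviral helicase gene induced by interferon that was in none of the lists, lay at −0.84 ± 0.20. PSMB9, a subunit of the immunoproteasome, was detected on 3 saline and 0 CpG-ODN arrays. Its bound was at least 1.64-fold lower, but the 95% interval of its log2 fold change, −1.36 to −0.48, also holds smaller changes. The small GTPase gene RAB12 lay at −0.92 ± 0.17, with −0.25 on its other probe, and the tenascin C gene TNC at −0.82 ± 0.17. NRGN, which encodes a calmodulin-binding protein, lay at −0.70 ± 0.15, the tRNA-modifying enzyme gene CDKAL1 at −0.73 ± 0.17 and LOC100506271 at −0.94 ± 0.21. The kinase gene MAP3K9 and LINC01089 were detected on 0 CpG-ODN arrays, with bounds of at least 1.42-fold and at least 1.30-fold lower. Their 95% intervals on the log2 scale, −1.17 to −0.34 and −1.05 to −0.27, also hold smaller changes.

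**Figure D1:**
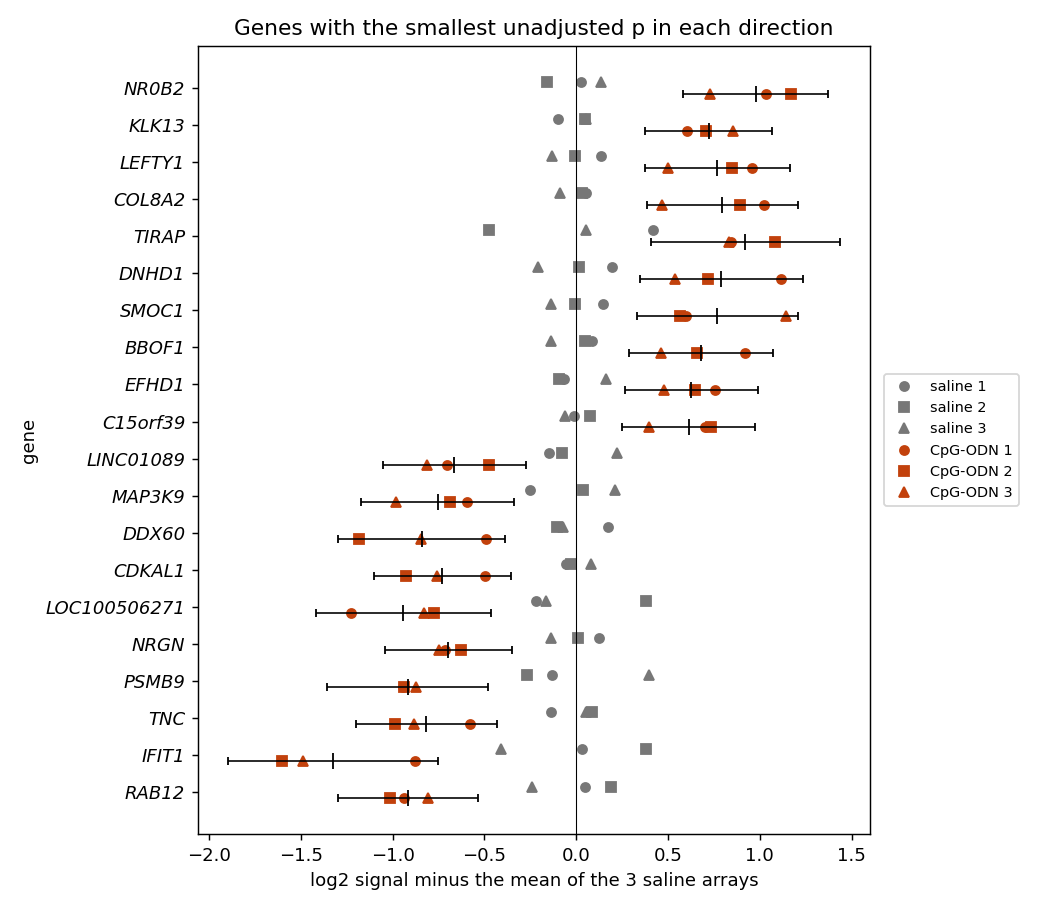
Log2 signal of each array minus the mean of the 3 saline arrays (horizontal axis) for the 10 genes with the smallest unadjusted p in each direction (vertical axis). Grey symbols are saline arrays, orange symbols are CpG-ODN arrays, and the black line is the fold change with its 95% interval; IFIT1 lay farthest from saline at −1.32, and none of the 20 genes passed the adjusted test.

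DNA repair genes lay on both sides of saline. Of 119 genes in the list 97 were measured, 54 with a higher and 43 with a lower mean in CpG-ODN, and 0 passed either over all genes tested or with p adjusted over the list alone. Their median log2 fold change was 0.02, and the list was not called against other genes (camera adjusted p = 0.894). The mean was −0.001, with the opposite sign, and with 1 array left out the median ran from −0.022 to 0.041. With scaling to equal medians it was 0.12, where the median of all genes was 0.085. For 94 of the 97 genes the 95% interval lay inside 2-fold, and for 54 inside 1.5-fold. The 2 repair genes with an unadjusted p under 0.05 were both lower: CLSPN, which encodes the checkpoint protein claspin, at −0.56 ± 0.16 (SE), and H2AX, the histone phosphorylated at DNA breaks, at −0.43 ± 0.19. The other probe of CLSPN gave 0.05. BRCA1 lay at 0.07 ± 0.16, with 0.28 on its other probe.

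In each part of the repair list 0 members were called. Homologous recombination and Fanconi anaemia genes had a median of 0.01 over 21 genes, with a mean and a test direction of the other sign (camera adjusted p = 0.735), and their leading members were BLM at −0.30 and MRE11 at 0.26. The other probes of MRE11 gave −0.32 and −0.60. Non-homologous end joining genes had a median of −0.15 over 7 genes (adjusted p = 0.719), with PRKDC at −0.40 and XRCC5 at −0.20. Mismatch repair genes had a median of 0.02 over 6 genes (adjusted p = 0.735), with PMS1 at 0.28 and EXO1 at −0.06. Base excision and single-strand break repair genes had a median of 0.03 over 20 genes (adjusted p = 0.529), with SMUG1 at 0.29 and NEIL1 at 0.29. Nucleotide excision repair genes had a median of 0.06 over 24 genes (adjusted p = 0.371), with GTF2H3 at −0.34 and CETN2 at 0.29. Damage signalling and translesion synthesis genes, which hold CLSPN and H2AX, had a median of −0.06 over 20 genes (adjusted p = 0.371). The medians with 1 array left out ran from −0.068 to 0.047 for homologous recombination, −0.26 to −0.022 for end joining, −0.050 to 0.090 for mismatch, 0.039 to 0.071 for base excision and −0.035 to 0.12 for nucleotide excision repair, and from −0.11 to −0.0054 for damage signalling. End joining genes turned to 0.093 with array weights and to 0.12 with CpG-ODN 3 as the only CpG-ODN array. With array weights homologous recombination turned to −0.042, nucleotide excision repair to −0.035 and damage signalling to 0.015. Median scaling moved the median of all genes to 0.085. End joining then lay at 0.083 and damage signalling at 0.038, and camera still gave both as lower than other genes. Mismatch repair turned to −0.063 with the mean of a gene's probes, and base excision repair stayed above 0 in all 18 alternatives.

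The receptor itself was not detected: the TLR9 probe was above background on 0 of 3 arrays in each group, as was that of CXCL10, a chemokine induced by interferon. Genes of the TLR9 pathway had a median of −0.11 over 19 measured genes, 5 higher and 14 lower (camera adjusted p = 0.371). The adaptor gene MYD88 lay at 0.37 ± 0.25 (SE), NFKB1 at −0.38 ± 0.17 and AP3B1, which takes part in sorting proteins to endosomes, at −0.41 ± 0.20. NF-kB and inflammatory genes had a median of −0.03 over 19 genes, 9 higher and 10 lower (camera adjusted p = 0.894), with a mean of 0.003. Their leading members went opposite ways: the cytokine gene IL6 lay at −0.53 ± 0.16 (unadjusted p = 0.0092) and the neutrophil chemokine gene CXCL5 at 0.43 ± 0.18 (unadjusted p = 0.045). CXCL8, another neutrophil chemokine, lay at 0.19 ± 0.19. Leaving out 1 array moved the median of the TLR9 pathway between −0.19 and 0.0081 and that of NF-kB genes between −0.054 and 0.086. Of these lists 0 members were called over all genes or over the list alone.

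Interferon-stimulated genes came closest to the threshold among the lists. Of 35 genes 23 were measured, 9 with a higher and 14 with a lower mean in CpG-ODN, and the median log2 fold change was −0.07 with a mean of −0.21. The list did not pass (camera adjusted p = 0.0785, from an unadjusted camera p of 0.00245). With an estimated correlation the camera p was 0.0323 unadjusted and 0.859 adjusted. The correlation estimated between its members was only 0.0036, so a high correlation does not account for the larger p. Over all genes 0 members were called, and adjusted over the list alone 1 was, IFIT1 (adjusted p = 0.0115). IFIT3 lay at −0.92 ± 0.29 (SE), with −0.65 on its other probe. IFIT2 at −0.61 and IFI44 at −0.44, named after their values were seen, were the other members with an unadjusted p under 0.05. The median of the list relative to the saline mean was −0.20, 0.09 and −0.15 in CpG-ODN arrays 1 to 3. The list passed without saline 3 (adjusted p = 0.0154, mean −0.234) and without CpG-ODN 2 (adjusted p = 0.00688, mean −0.227). Its adjusted p was 0.143 without saline 1, 0.206 without saline 2, 0.383 without CpG-ODN 1 and 0.134 without CpG-ODN 3, with means of −0.191, −0.197, −0.187 and −0.207, while the median ran from −0.12 without CpG-ODN 2 to −0.053 without CpG-ODN 1. The list also passed with median scaling (camera adjusted p = 0.00223), without a filter (0.00437), with the replicate block (0.0480) and with the brightness covariate (0.0406). Median scaling moved the median of all genes to 0.085 and that of ribosomal proteins to 0.38. The mean of the interferon list then shrank to −0.158, so that pass does not show a larger drop of its members. Its mean shrank to −0.116 with the deposited values and to −0.088 with the stricter detection filter, where it did not pass.

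Genes of the cell cycle and of the p53 response did not pass either. Mitosis genes had a median of −0.06 over 25 genes, 19 of them lower (camera adjusted p = 0.371), with the spindle factor TPX2 at −0.33 and the kinetochore protein gene CENPF at −0.34. S-phase genes had a median of −0.12 over 20 genes, 15 of them lower (camera adjusted p = 0.284), with the replicative helicase subunits MCM4 at −0.31 and MCM3 at −0.24. The other probe of MCM4 gave 0.01. The proliferation marker MKI67 lay at 0.01 ± 0.22 (SE). Targets of p53 had a median of −0.08 over 20 genes, 12 of them lower (camera adjusted p = 0.371), with SESN1 at −0.37, POLH at −0.44 and the cyclin-dependent kinase inhibitor CDKN1A at −0.22 ± 0.15. The median of mitosis genes with 1 array left out ran from −0.13 without CpG-ODN 1 to −0.0085 without CpG-ODN 2, that of S-phase genes from −0.18 without CpG-ODN 3 to −0.062 without CpG-ODN 2 and that of p53 targets from −0.15 to −0.048; S-phase genes lay at −0.035 with array weights and at −0.00089 in CpG-ODN 3 alone. Scaling to equal medians in place of quantile normalization moved the median of all genes to 0.085, and the medians of these 3 lists then lay at 0.12, 0.086 and 0.027.

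**Figure D2:**
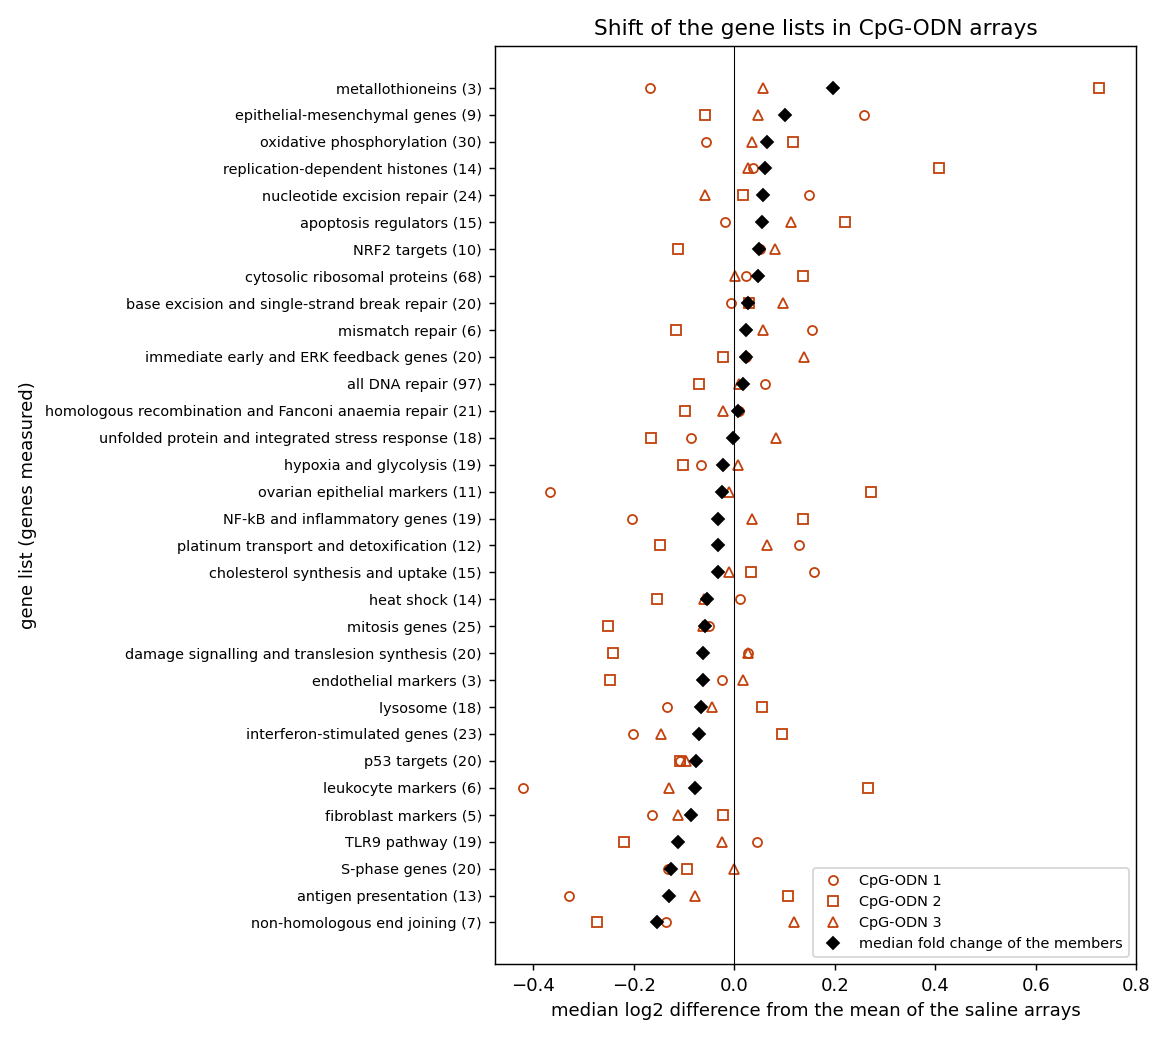
Median log2 difference from the mean of the saline arrays (horizontal axis) for each of the 32 gene lists (vertical axis, with the number of genes measured). Black diamonds are the median fold change of a list's members and open symbols are the medians in each CpG-ODN array; the diamonds lie between −0.15 and 0.20, and in many lists CpG-ODN 1 and 2 lie on opposite sides of 0.

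The CpG-ODN arrays differed more among themselves than the saline arrays did. Across genes, pairs of saline arrays correlated at 0.990 to 0.992 and pairs of CpG-ODN arrays at 0.965 to 0.984. The differences between CpG-ODN 1 and CpG-ODN 2 had a standard deviation of 0.583 log2 units, against 0.281 to 0.316 for the saline pairs. On the first principal component, with 47.0% of the variance, CpG-ODN 1 scored −31.7 and CpG-ODN 2 scored 29.0, on either side of CpG-ODN 3 at 5.36 and of the saline arrays at −9.65, −0.14 and 7.16. With array weights estimated in limma, which gave CpG-ODN 3 a weight of 5.25 against 0.244 for CpG-ODN 1 and 0.335 for CpG-ODN 2, the count of called genes was 76, with 48 higher and 28 lower. IFIT1, TNC, SMOC1 and KLK13 were among these, each with an adjusted p of 0.0272. With these weights the CpG-ODN side rests mainly on CpG-ODN 3, so the calls come close to 1 CpG-ODN array against saline. A split that mixed saline and CpG-ODN arrays called 922 genes with array weights, so the 76 calls are weak evidence of a treatment effect.

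**Figure D3:**
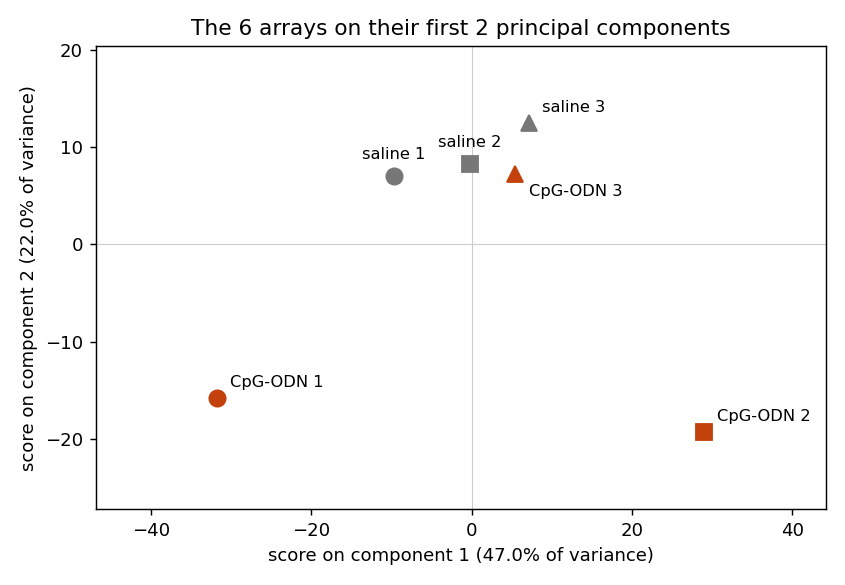
Scores of the 6 arrays on the first (horizontal axis) and second (vertical axis) principal component of the log2 signals, with the percent of variance in each axis label. Grey symbols are saline arrays and orange symbols CpG-ODN arrays; CpG-ODN 1 at −31.7 and CpG-ODN 2 at 29.0 lie apart on the first component and CpG-ODN 3 at 5.36 lies near the saline arrays.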

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

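The array weights, the other single changes and the arrays left out were planned; the tests without CpG-ODN 1 and 2 together and with the brightness covariate were chosen after the data had been examined. The fit without CpG-ODN 1 and 2 compares 1 CpG-ODN array with 3 saline arrays, takes its spread from the saline arrays alone and is a weak test. The count of called genes was 0 in limma in every alternative run except array weights, which gave 76 genes (48 higher, 28 lower). The weights let CpG-ODN 3 count far more than CpG-ODN 1 and 2, so this too is a weak test. The count at an unadjusted p under 0.05 ran from 150 with median scaling to 1891 with array weights, against 395 in the main fit. It was 1037 without CpG-ODN 1, 214 without saline 3 and 1210 with the brightness covariate. None of the 7 main lists passed in any alternative except the interferon-stimulated genes, which passed in 6 of 18 and lay lower in all 18, with adjusted p from 0.00223 to 0.383. Their median was −0.049 with median scaling, −0.089 without a filter, −0.070 with the replicate block (adjusted p = 0.0480) and −0.21 with the brightness covariate, and −0.12 to −0.053 with 1 array left out. It was −0.032 with the deposited normalized values and without background correction, and −0.033 over 17 genes with the stricter detection filter (adjusted p = 0.344), where the mean was −0.088 against −0.207. With an estimated correlation or with fry 0 lists passed (interferon-stimulated genes: adjusted p = 0.859 and 0.845). With median scaling, which moved the median of all genes to 0.085, mitosis genes lay at 0.12, S-phase genes at 0.086 and p53 targets, still lower than other genes in camera, at 0.027. All DNA repair then lay at 0.12, against 0.017 in the main fit. Base excision and nucleotide excision repair both lay at 0.18, and none of these repair lists passed. The sign of other uncalled medians turned: with the brightness covariate mitosis genes lay at 0.018; with array weights NF-kB genes lay at 0.0060 and without CpG-ODN 1 and 2 at 0.036. With 1 array left out all DNA repair ranged from −0.022 to 0.041, TLR9 pathway from −0.19 to 0.0081 and NF-kB genes from −0.054 to 0.086. The cause of these turns was not tested.

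Median scaling also called oxidative phosphorylation (median 0.34) and ribosomal proteins (median 0.38). Antigen presentation passed without CpG-ODN 2 (median −0.21, adjusted p = 0.00514) and with the brightness covariate (adjusted p = 0.00442), with a range up to 0.880. Of 1499 values of single named genes, 1472 kept their sign, and 14 passed the threshold, all with array weights. Most of these genes were picked for a small unadjusted p in the same arrays, so the kept signs are weak evidence. Of 496 values of the other lists, 434 kept their sign and 4 passed. The numbers were not taken as pairs in the main fit, which was set before the data were examined. Arrays with the same number deviated together with correlations of 0.370, 0.0457 and 0.110 across genes, and CpG-ODN 2 correlated best with saline 3 (0.285). These values leave open whether the numbers mark pairs. The replicate block gave 0 called genes and 536 at an unadjusted p under 0.05. A block for the chip was not run, because no chip is named. Between 35.1% and 38.5% of the probes were above background per array, which limits what can be said of dim genes.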

Other observations

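The tests on bright and dim interferon-stimulated genes and on other splits of the arrays were chosen only after the result was seen. Among the lists not described so far, 0 passed in camera. Antigen presentation genes had a median log2 fold change of −0.13 over 13 genes, 10 of them lower (camera adjusted p = 0.230, and 0.859 with an estimated correlation), with PSMB9 called over the list alone (adjusted p = 0.0134) and HLA-C at −0.26. Epithelial-mesenchymal genes had a median of 0.10 over 9 genes (adjusted p = 0.371), and the transcription factor genes SNAI2 at 0.79 ± 0.32 (SE) and ZEB2 at 0.51 ± 0.21 both had an unadjusted p under 0.05; the other probe of SNAI2 gave 0.06. Immediate early and ERK feedback genes had a median of 0.02 over 20 genes (adjusted p = 0.735), with the ERK phosphatase gene DUSP4 at −0.73 ± 0.20 and JUN at 0.39 ± 0.18. Hypoxia and glycolysis genes had a median of −0.02 over 19 genes and a mean of 0.003 (adjusted p = 0.894), with the oxygen-sensing hydroxylase gene EGLN3 at 0.76 ± 0.24 and ANKRD37 at 0.30. Cholesterol synthesis genes had a median of −0.03 over 15 genes and a mean of 0.01 (adjusted p = 0.735), with MVD at 0.51 and FDPS at 0.33. These medians with 1 array left out ran from −0.21 to −0.035 for antigen presentation, which passed without CpG-ODN 2 (adjusted p = 0.00514), 0.035 to 0.20 for epithelial-mesenchymal, 0.020 to 0.065 for immediate early, −0.058 to −0.013 for hypoxia and −0.050 to 0.059 for cholesterol genes.

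The lists on stress, metabolism, RNA quality and cell types did not pass either. The median was −0.05 for heat shock (HSPA6 at −0.38, CRYAB at 0.43), −0.002 for the unfolded protein response (EDEM1 at −0.43, PSAT1 at −0.30) and 0.05 for NRF2 targets (HMOX1 at 0.24, NQO1 at −0.22 and, on its other probe, 0.27). It was 0.20 for 3 metallothioneins (MT2A at 0.29, MT1F at −0.18), −0.07 for lysosomal genes (CTSD at −0.36, PSAP at −0.20) and 0.06 for apoptosis regulators (CFLAR at 0.34, BAK1 at 0.23). It was −0.03 for platinum transport and detoxification (ABCC4 at −0.22 and, on its other probe, 0.16, ATP7B at −0.17) and 0.07 for oxidative phosphorylation (COX5A at 0.24, NDUFB5 at 0.22). Lists on RNA quality lay at 0.05 for ribosomal proteins (camera adjusted p = 0.230; RPS26 at 0.34, RPL36 at 0.25) and 0.06 for replication-dependent histones (H3C4 at −0.68, H1-2 at 0.37). Markers of ovarian epithelium had a median of −0.02 over 11 genes (MUC1 at −0.37, ELF3 at −0.35). Those of other cell types lay at −0.08 for leukocytes (CD14 at −0.32, CD68 at 0.27 and, on its other probe, −0.14), −0.09 for fibroblasts (PDGFRA at 0.36, THY1 at −0.18) and −0.06 for endothelium (VWF at −0.41, PECAM1 at 0.36), each on 3 to 6 measured genes. The lowest adjusted p among the lists of this paragraph was 0.230, and 0 of their members were called over the list alone. The sign of the median turned with at least 1 of the arrays left out for the unfolded protein response, metallothioneins, apoptosis regulators, platinum transport, histones and the markers of ovarian epithelium, leukocytes and endothelium.

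CpG-ODN arrays 1 and 2 lay apart from the other arrays in opposite directions. Noise of dim probes was argued against, since in the brightest of 4 equal parts of the genes the spread of their differences was still 2.20 times that of the widest saline pair. On the second principal component both lay on one side of the saline arrays, at −15.7 and −19.3, with CpG-ODN 3 at 7.20, and whether they share part of a response was not tested. A different state of the cells may contribute and stays open: 4 of the 32 lists differed between the 2 arrays beyond 95% of random lists. For lists of unrelated genes 1.6 would be expected, and genes of 1 list can move together. The lists were leukocyte markers (6 genes), metallothioneins (3 genes), antigen presentation and ribosomal proteins. A difference in handling or in the dose that reached the cells was not tested.

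The spread between these arrays is a candidate explanation for the low number of small p-values. The share of genes at an unadjusted p under 0.05 was 3.58% with all arrays, 9.39% without CpG-ODN 1, 4.40% without CpG-ODN 2 and 5.36% without CpG-ODN 3. With all arrays and the brightness covariate, chosen after the data had been examined, it was 10.96%, above every fit with 1 array left out. Array brightness was therefore not told apart from the spread between these arrays. The rise without CpG-ODN 1 is consistent with opposite deviations widening the residual spread, but a rise was also seen without CpG-ODN 3, which did not lie apart. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 genes and the highest other split 0, a comparison that says nothing about chance. At an unadjusted p under 0.05 the real split gave 395 genes and the highest other split 1408, with 4 of 10 giving as many. With array weights the real split called 76 genes and the highest other split 922, with 4 of 10 giving as many, and the split with 922 set saline 1, CpG-ODN 2 and CpG-ODN 3 against the rest. Without weights that split called 0 genes and had 301 at an unadjusted p under 0.05, so its count came with the weights; what structure of the arrays lies behind it was not tested.

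The lower interferon-stimulated genes in CpG-ODN are a hypothesis from these data, and a biological effect of the treatment is among the open explanations. Among 6 members brighter than the median tested gene the median log2 fold change was 0.05 with a camera p of 0.376, and among the 17 dimmer members it was −0.25 with a camera p of 3.89e-05 (0.0172 with an estimated correlation). All 14 members that lay lower were among the 17 dimmer ones, and the 6 brighter members all lay higher. That 14 of 17 went one way goes against noise that scatters both ways. A shift shared by dim probes was not tested, since equally dim genes outside the list were not compared. The list was also singled out as the one with the smallest p of 32. Its bright members are few, so noise of dim probes stays open. With 1 array left out the mean of the list stayed between −0.234 and −0.187, against −0.207 with all arrays, while its median ran from −0.12 to −0.053 against −0.070 and lay at 0.09 in CpG-ODN 2 alone; the camera p rose to 0.0673 without CpG-ODN 1 and stayed under 0.05 without any other single array, so how far the p rests on that array stays open. The real split gave a camera p of 0.00245, the smallest of the 10 splits (1 of 10, the real one), and the next was 0.00510; the splits are too few for a share under 0.05.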
